A study of Mus musculus with 6 samples.

How the data were processed

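Gene expression was measured in whole brains of mice carrying 1 disrupted copy of the periphilin gene (Pphln1) and of wild-type C57BL/6 littermates. Each brain was hybridised to 1 Affymetrix array, with 3 brains per genotype, so the 6 arrays are separate animals. Per the labels, the mice were 2 months old and male, RNA was purified from snap-frozen tissue, and biotin-labelled cRNA was made with an oligo(dT) primer, a protocol that favours the 3' ends of transcripts.

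The values are the authors' deposited probe-set intensities, 1 linear value per probe set and array. The software that summarised the probes was not given in the sources used here, and detection calls were not used here. The mean of the central 96% of the values came to 150.0 on every array, so the deposited intensities had been scaled to a common level. Array medians ranged from 31.2 to 34.5. The number of arrays, 3 per genotype, limits the precision.

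The table held 45101 probe sets. The 64 control probe sets of the manufacturer were set apart for quality checks. Of the other 45037, the platform annotation gave 1 gene for 34945, several genes for 932, and 9160 are not named here. Symbols were updated through Entrez identifiers, of which 34741 matched a RefSeq gene table of assembly GRCm38.p6. That table was used for names, chromosomes, gene starts and the order of neighbouring genes. The starts defined the windows around Pphln1 and Mtmr7 and the bins of 1 Mb. A probe set with several genes was never given a gene name.

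Intensities were transformed as log2(value + 16), so fold changes of dim probe sets are understated. No further normalization was applied because the medians of the log2 values differed little between arrays. Probe sets whose mean lay at or below the 40th percentile, a signal of 18.4, were removed as dim (18015), which left 27022 tested, 23473 of them with 1 gene. Genotypes were compared with limma (version 3.58.1, R 4.3.3), with lmFit and eBayes with an intensity trend and no covariate. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. For single values, two-sided exact permutation tests were run. With 3 against 3 brains their smallest possible p is 0.1.

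For gene lists, each gene was represented by its brightest tested probe set (13024 genes). The 38 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The lists covered partners of periphilin, gene families chosen for a possible link to its complex, stress and housekeeping pathways, synapses, brain cell types, brain regions and tissues a dissection could include. Genes whose start lay within 10 Mb of Pphln1 on chromosome 15 formed a further set, tested with Fisher's exact test on the share at an unadjusted p below 0.05.

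The genes named were chosen by a fixed rule. Each Pphln1 probe set is given, with Tasor, Mphosph8, Setdb1 and Morc2a. Then come up to 10 genes per direction past the adjusted threshold, ordered by size. Places left were filled with the smallest unadjusted p among probe sets with non-overlapping genotypes and a log2 difference of at least 0.5 in size, stated to have missed the threshold. The 2 highest and 2 lowest members of each list by moderated t are given, as are neighbours of Pphln1 past the threshold adjusted over that set alone. The lists, the rule, the tests and most alternatives were set before the data were examined.

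The steps were tested on simulated data for the same 27022 probe sets and 6 arrays, with 200 changed probe sets in each of 20 runs. With spreads drawn from the distribution limma fitted, 99.3% of changes of 2 on the log2 scale were recovered, 73.8% of changes of 1 and 0.225% of changes of 0.5. False calls made up 5.29% of calls at a change of 2 and 4.50% at a change of 1, and with no change no run gave a call. When each probe set was given its own shrunken spread, 89.3% of changes of 1 and 19.2% of changes of 0.5 were recovered. False calls then made up 7.54% of calls at a change of 2 and 13.8% at 0.5, and runs with no change gave 1.45 calls on average. A list of oxidative phosphorylation genes shifted by 0.2 was called in 100% of runs. The simulated noise was independent between probe sets, whereas the measured list was correlated at 0.33 with a median log2 difference of 0.09. Those runs therefore cannot show how reliable a camera call is for correlated lists.

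Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, other filters on dim probe sets, eBayes without trend or with robust fitting, array weights, a replicate block, statistics without moderation, a looser threshold, leaving out each array in turn and, for lists and neighbours, other set tests and windows. The 18S ribosomal RNA signal as a covariate was added after the data had been seen. No array was left out of the main comparison.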

Results

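The data comprised 6 whole-brain expression profiles, 3 from heterozygous periphilin knockout mice and 3 from wild-type littermates, each from its own array. Periphilin, encoded by Pphln1, is a subunit of the HUSH complex, which silences retroelements and some genes through histone methylation. The comparison asked how the brain transcriptome of heterozygous mice differs from that of their littermates. Between any pair of arrays, the log2 values correlated at 0.978 to 0.985.

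The signal of Pphln1 itself did not pass the test at either of its probe sets. At 1434822_at it was 319.8 ± 44.5 (SD, n = 3) in heterozygous brains and 299.7 ± 12.6 (n = 3) in wild-type brains. That is a log2 difference of 0.08, with a 95% confidence interval of -0.17 to 0.33 (limma adjusted p = 0.969), and the exact permutation p was 0.6. As a ratio on the same scale it was 1.06, with limits of 0.89 to 1.26, which exclude a halving of the signal at this probe set. At the dimmer 1435766_at it was 37.2 ± 6.91 against 52.3 ± 9.50, lower in each heterozygous brain than in any wild-type brain. The log2 difference there was -0.36, with an interval of -0.75 to 0.03 (limma adjusted p = 0.956), and the exact permutation p of 0.1 is the smallest that 3 against 3 brains can give. Fold changes of dim probe sets are understated on this scale, so the interval at 1435766_at cannot exclude a halving. Where the disruption lies in the gene is not given in the sources used here, so a probe set outside the disrupted part would not check the genotype.

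Across the transcriptome, 3 probe sets rose and 1 fell in heterozygous brains. Mtmr7, a phosphoinositide phosphatase of the myotubularin family, rose most: 1447831_s_at measured 269.6 ± 30.5 (n = 3) in heterozygous and 23.3 ± 4.56 (n = 3) in wild-type brains, 7.26-fold on the log2(value + 16) scale (log2 difference 2.86, SE 0.15, limma adjusted p = 1.81e-05). The wild-type signal lies near the dim limit of 18.4, and the log2 difference of Mtmr7 was 1.93 with a pseudocount of 64 and 3.48 with a pseudocount of 1. Prune2, a protein abundant in the nervous system, rose from 1297 ± 32.8 to 2264 ± 221 at 1432198_at, a log2 difference of 0.79 (SE 0.09, limma adjusted p = 0.0192). Yaf2, a component of variant Polycomb complexes, fell from 1746 ± 58.8 to 1099.6 ± 13.1 at 1423399_a_at, a log2 difference of -0.66 (SE 0.08, limma adjusted p = 0.0196). A probe set not named here, 1439170_at, rose from 107.6 ± 13.5 to 253 ± 18.8, a log2 difference of 1.13 (SE 0.12, limma adjusted p = 0.0192). Each of the 4 differed in the same direction between every heterozygous and every wild-type brain.

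Other probe sets of the same genes went along in part. The second Mtmr7 probe set, 1427025_at, was brighter in both genotypes, at 418.6 and 347.2, with a log2 difference of 0.25 (SE 0.10). The other tested Prune2 probe sets lay at -0.15 (SE 0.18) and -0.43 (SE 0.12), opposite in sign to the called one. The second Yaf2 probe set, 1429839_a_at, lay at -0.52 (SE 0.07), and its limma adjusted p of 0.119 missed the threshold. Leaving out 1 array at a time gave 14 calls without heterozygous 1, 1 without heterozygous 2, 2 without heterozygous 3, 3 without wild type 1, 3 without wild type 2 and 2 without wild type 3. Mtmr7 was called in each of these fits, Prune2 and Yaf2 without heterozygous 1 alone, and 1439170_at without heterozygous 1 and without wild type 2.

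**Figure D1:**
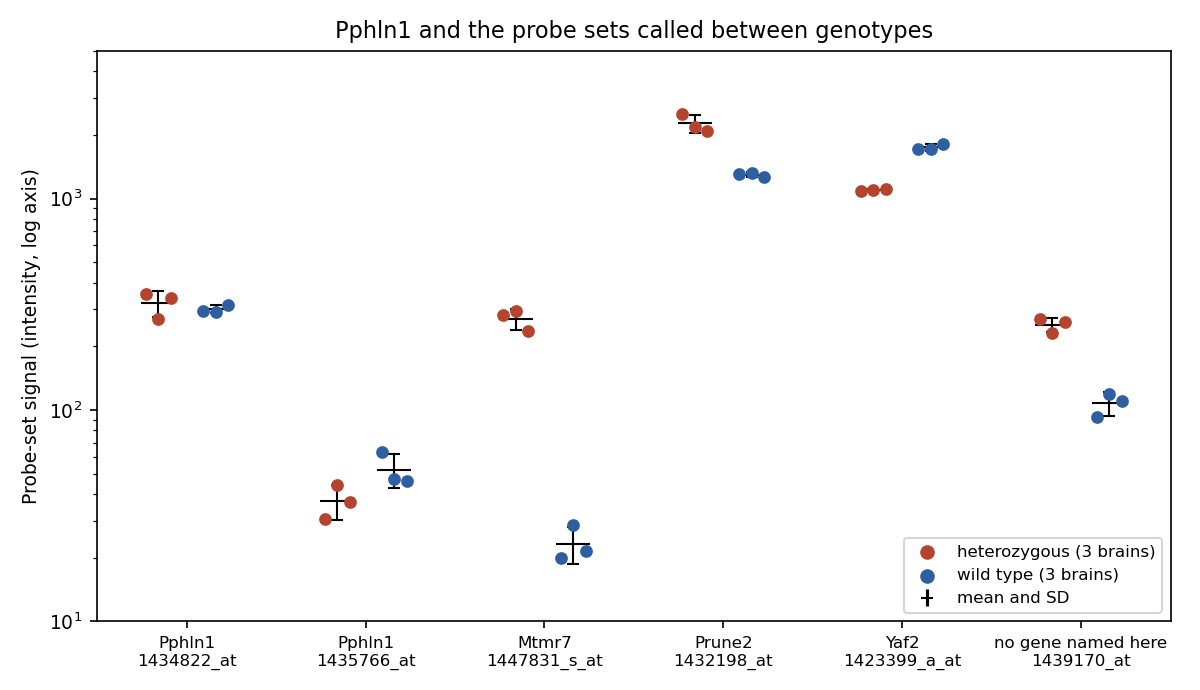
Probe-set signal (intensity, log axis) of Pphln1 and of the probe sets called between genotypes; points are single brains, 3 heterozygous and 3 wild type per probe set, and bars are mean and SD. The heterozygous brains sit above the wild-type brains for Mtmr7 (mean 269.6 against 23.3) and below them for Yaf2 (1099.6 against 1746), while both genotypes overlap at the brighter Pphln1 probe set.

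Genes that missed the threshold were named by unadjusted p, and none of their values is a call. Among those higher in heterozygous brains, Zdhhc12, a palmitoyltransferase gene, had a log2 difference of 1.36 (SE 0.23), from 19.6 to 77.8, and of 0.75 and 1.89 with pseudocounts of 64 and 1. Unc13a, which encodes a synaptic vesicle priming protein, was at 0.55 (SE 0.10), the adenylyl cyclase gene Adcy3 at 0.52 (SE 0.10) and Dlc1 at 0.66 (SE 0.15). The other tested probe sets of Adcy3 lay at -0.11, 0.23 and -0.03, and those of Dlc1 at 0.54 and 0.00. Rab3a, a synaptic vesicle GTPase gene, was at 1.11 (SE 0.26) by 1459980_x_at and at 0.12 (SE 0.09) by its other probe set. Unc13a, Dlc1 and Rab3a lie on chromosome 8, as does Mtmr7. The peroxisomal transporter gene Abcd2 was at 0.68 (SE 0.14) by 1456812_at and at -0.45 (SE 0.14) by 1438431_at. Krtap12-1, at 1.19 (SE 0.28), and the gap junction gene Gjd2, at 0.81 (SE 0.19), were dim, with heterozygous means of 46.2 and 30.0, and wild-type means of 10.8 and 10.3, below the dim limit. With a pseudocount of 64 they lay at 0.55 and 0.34, and Krtap12-1 at 2.06 with a pseudocount of 1. The brighter Gjd2 probe set lay at 0.07 (SE 0.17).

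On the lower side, Ddo, which encodes D-aspartate oxidase, was at -0.92 (SE 0.14), from 168.5 to 81.6, although its second tested probe set lay at 0.12. Gabra2, a subunit of the GABA-A receptor, was lower at each of its 3 tested probe sets, at -0.62 (SE 0.12), -0.56 (SE 0.13) and -0.34 (SE 0.16). The linker histone gene H1f2 was at -0.69 (SE 0.16) and -0.53 (SE 0.22) by its tested probe sets. Ptchd1 was at -0.60 (SE 0.12), with its other 3 probe sets between 0.01 and 0.18, and the proteasome gene Psmb1 was at -0.95 (SE 0.19) by 1420052_x_at, -0.53 with a pseudocount of 64, and at -0.05 by its brightest probe set. Gxylt1 was at -0.64 (SE 0.13), Mad1l1, a spindle checkpoint gene, at -0.59 (SE 0.14; -0.37 with a pseudocount of 64) and Frg1 at -0.50 (SE 0.11). Minar2 was at -2.14 (SE 0.50) by 1437528_x_at, where heterozygous 1 measured 505.6 and the other heterozygous brains 79.5 and 79.4. Its other tested probe sets lay at 0.07 by 1433577_at and at -0.42 (SE 0.29) by 1444082_at.

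Without adjustment, 1306 of the 27022 probe sets had a limma p below 0.05, 657 higher and 649 lower, where 1351 were expected with no difference. A log2 difference of at least 1 in size was seen for 31 probe sets, and a fold of at least 1.5 for 256. The genotypes did not overlap for 10.2% of probe sets, and chance gives 10%.

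On chromosome 15, the 3 protein-coding genes that precede Pphln1 in the RefSeq gene order fell in heterozygous brains when adjusted over the neighbours alone. Zcrb1, a protein of the minor spliceosome, lies next to Pphln1 and fell from 1369.7 ± 61.1 to 1001 ± 79.1 (n = 3 each), a log2 difference of -0.45 (SE 0.09, limma adjusted p = 0.0283 over the set alone). Yaf2 comes next and fell from 2399 to 1667 (n = 3 each) at its brightest probe set (-0.52, SE 0.07, limma adjusted p = 0.00402). Gxylt1, a xylosyltransferase that modifies Notch, is the third and fell from 164 ± 16.6 to 99.3 ± 12.2 (-0.64, SE 0.13, limma adjusted p = 0.0295). Over all probe sets, these values of Zcrb1, Yaf2 and Gxylt1 missed the threshold (limma adjusted p = 0.656, 0.119 and 0.768). On the other side of Pphln1, Prickle1 lay at -0.06 (SE 0.09) and Adamts20 at 0.09 (SE 0.16).

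Of the 183 measured genes within 10 Mb, 15 had a p below 0.05, 11 of them lower, among them Nell2 at -0.34 and Tmem117 at -0.41, and 4 higher, including Pou6f1 at 0.34 and Letmd1 at 0.37. The other tested Nell2 probe set lay at -0.015 (SE 0.20). Abcd2 counted as lower by its brightest probe set, 1438431_at (-0.45), whereas 1456812_at lay at 0.68 and 1419748_at at 0.20. The 15 genes include Zcrb1, Yaf2 and Gxylt1. The share within 10 Mb, 8.20%, compares with 4.33% of all other genes (two-sided Fisher's exact test, p = 0.0172). Within 5 Mb it was 12.5% (Fisher's exact p = 0.00661). Without Zcrb1, Yaf2 and Gxylt1, the share within 5 Mb was 8.20% against 4.34% of other genes (Fisher's exact p = 0.192). The median log2 difference within 10 Mb was 0.02, and camera called neither the 10 Mb nor the 5 Mb set. The share lost its call within 20 Mb (5.60%, Fisher's exact p = 0.280), without heterozygous 1 (7.10%, p = 0.0565) and without wild type 3 (6.01%, p = 0.111). It was also lost without the dim filter (p = 0.0556), with the replicate block (p = 0.0960), without moderation (p = 0.118) and with the 18S signal as covariate (p = 0.167), by the same Fisher's exact test.

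**Figure D2:**
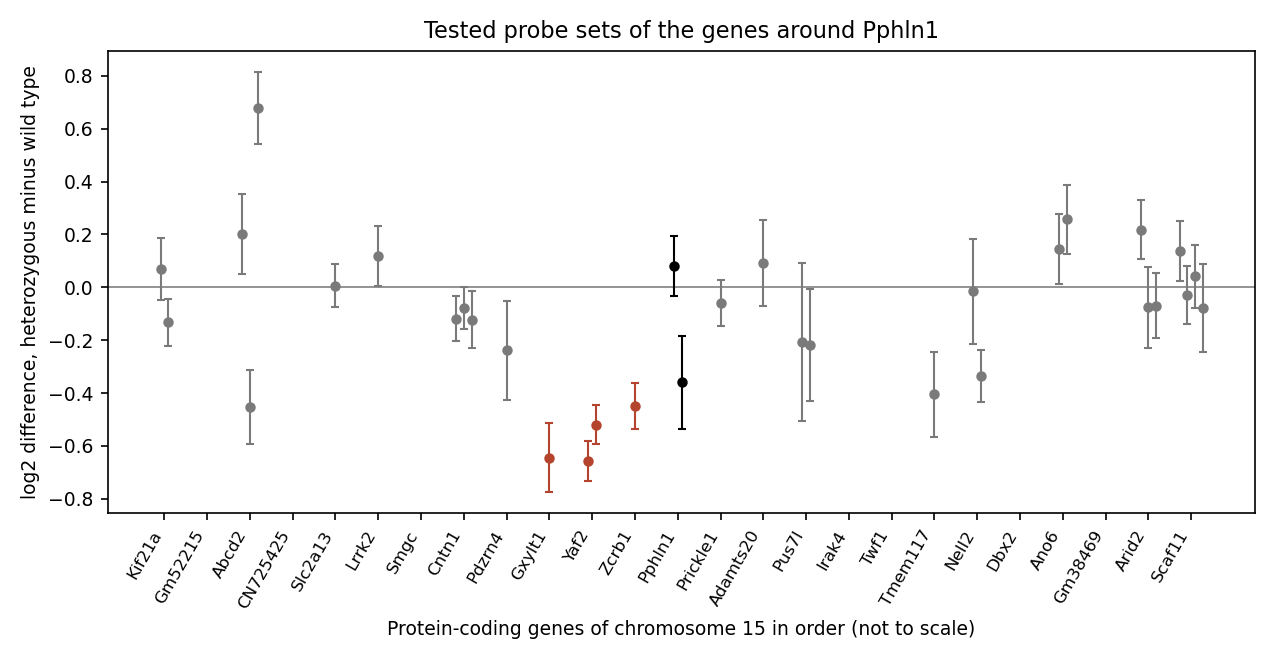
Log2 difference, heterozygous minus wild type, with SE, of each tested probe set (points) of the protein-coding genes around Pphln1 on chromosome 15, in gene order and not to scale. Gxylt1 (-0.64), Yaf2 (-0.66 and -0.52) and Zcrb1 (-0.45), in red, lie below 0 beside Pphln1 (black, 0.08 and -0.36), and genes without a point had no tested probe set.

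None of the 17 measured genes of the HUSH complex and its partners was called, over all probe sets or adjusted over the list alone. In sign, 12 were higher and 5 lower (median log2 difference 0.05, camera adjusted p = 0.335). Setdb1, the histone methyltransferase that works with HUSH, was at 0.36 (SE 0.13), and Morc2a, a chromatin-compacting ATPase gene, at 0.22 (SE 0.11). The HUSH subunits Tasor and Mphosph8 lay at 0.05 (SE 0.12) and -0.06 (SE 0.09), and the heterochromatin protein genes Cbx1 and Cbx5 were lowest, at -0.24 (SE 0.20) and -0.12 (SE 0.11). Limma's fry, which asks whether members move on balance in 1 direction without comparing them with other genes, gave an adjusted p of 0.0155.

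Lists of gene families chosen for a possible link to HUSH silencing did not pass either. They hold annotated genes, and the expression of retroelements themselves was not examined here. Of 16 clustered protocadherins, 12 were lower in sign (median -0.13, camera adjusted p = 0.335), from Pcdhb16 at -0.35 and Pcdhb21 at -0.27 to Pcdhb15 at 0.10 and Pcdhb2 at 0.39. The protocadherin list was called in 1 of 19 alternatives (lowest camera adjusted p = 0.0484). The 302 measured zinc finger genes had a median of -0.02 (camera adjusted p = 0.709), with Zfp37 at -0.37 and Zfp423 at -0.60 lowest by test statistic and Zfp692 at 0.46 and Zfp983 at 0.48 highest. Among 10 genes of retroviral origin (camera adjusted p = 0.709), Fv1, a retrovirus restriction gene, lay at -0.91 (SE 0.27, limma adjusted p = 0.0557 over the list alone) and Pnma2 at -0.16, with Rtl8c at 0.14 and Ldoc1 at 0.21. Among 32 imprinted genes (camera adjusted p = 0.849), Meg3 was at 0.37, Mirg at 0.35, Plagl1 at -0.21 and Ddc at -0.20.

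Of the 38 lists, genes of oxidative phosphorylation alone passed the threshold, on the higher side, with 57 of 77 members higher in sign (median log2 difference 0.09, camera adjusted p = 0.000489). The list's members were correlated at 0.33, and the call was lost with an estimated correlation (adjusted p = 0.844) and by fry (adjusted p = 0.947). The median was 0.05 under quantile normalization and under median centring, and 0.05 to 0.13 with single arrays left out. No member passed over all probe sets or over the list alone. Ndufa4, at 0.25 (SE 0.09), and Ndufv1, at 0.20 (SE 0.09), were highest, and Sdhc at -0.13 and Cox5a at -0.10 lowest. The call was also lost without heterozygous 2 (adjusted p = 0.450), wild type 1 (0.247) or wild type 3 (0.144).

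The other 37 lists had camera adjusted p from 0.335 to 0.990, and no member of any tested list was called over all probe sets. Adjusted over the list alone, 35 of the 38 lists held no call. That adjustment does not correct for looking at 38 lists, so some such values can arise with no difference. In the synaptic vesicle list, Unc13a was higher (0.55, limma adjusted p = 0.00561 over the list alone and 0.541 over all probe sets), with Cplx1 at 0.17, Slc17a7 at -0.27 and Syt11 at -0.13. Gabra2 was lower among 26 genes of GABA signalling and interneurons (-0.56, limma adjusted p = 0.0358 over the list alone and 0.956 over all probe sets). Slc32a1 was at -0.17, Gabra3 at 0.15 and Gabrg1 at 0.18. Nrgn, a postsynaptic calmodulin-binding protein, was lower among 25 neuron markers (-0.37, SE 0.09, limma adjusted p = 0.0344 over the list alone), with Vsnl1 at -0.08, Uchl1 at 0.20 and Meg3 at 0.37. Among glutamate receptors and scaffolds, Camk2a was at 0.47, Gria1 at 0.16, Grin2b at -0.29 and Dlgap1 at -0.18.

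Markers of glia and vessels showed no called shift. Among astrocyte markers, Gfap was at -0.40 and Slc1a3 at -0.27, with Aldoc at 0.16 and Acsbg1 at 0.25. Gfap was higher on heterozygous 1, wild type 1 and wild type 3 (712.2, 795.9 and 802.5) than on the other arrays (440.7 to 522.2). Myelin genes ranged from Ermn at -0.26 and Cryab at -0.30 to Mbp at 0.10 and Enpp6 at 0.15, and oligodendrocyte precursor genes from Matn4 at -0.22 and Olig2 at -0.14 to Vcan at 0.22 and Lhfpl3 at 0.24. Microglial Sall1 and Fcer1g were at -0.25 and -0.26, Cd68 at 0.21 and Fcrls at 0.22. Endothelial Flt1 and Itm2a were at -0.24 and -0.11, Kdr at 0.33 and Vtn at 0.08.

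Regional markers were likewise without a called shift. For the cerebellum the extremes were Fat2 at 0.35, Zic2 at 0.26, En2 at -0.30 and Tmem132d at -0.14. For the striatum they were Drd2 at 0.20, Rasd2 at 0.19, Ido1 at -0.21 and Tac1 at -0.14, and for hippocampus and cortex Camk2a at 0.47, Rorb at 0.24, Neurod6 at -0.27 and Crym at -0.18. In the olfactory bulb list Omp was at -0.54, Slc17a7 at -0.27, Lbhd2 at 0.46 and Doc2g at 0.29. Thalamic Gbx2 and Prkcd were at 0.27 and 0.17, Gpr151 at -0.28 and Tcf7l2 at -0.20. Dopaminergic En2 and Ddc were at -0.30 and -0.20, with Kcnj6 at 0.27 and Drd2 at 0.20. The list of hypothalamus and brainstem genes included Pmch at 0.23, Sim1 at 0.40, Gpx3 at -0.21 and Pomc at -2.09 (SE 1.03). Pomc measured 4380.1 in wild type 1 and 62.2 to 130.3 in the other brains.

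Stress, signalling and housekeeping lists did not pass. Interferon-linked Bst2 and Gbp2 were at -0.52 and -0.41, against Stat2 and Oas1a at 0.25 each. Among chaperones and endoplasmic reticulum stress genes, Pdia4 was at 0.41, Pdia6 at 0.22, Canx at -0.26 and Hsp90b1 at -0.18. Among glucocorticoid-responsive genes Pdk4 was at -0.43, Ddit4 at -0.16, Klf15 at 0.29 and Zbtb16 at 0.22. Immediate early genes ranged from Fosl2 at -0.32 and Jund at -0.21 to Ier2 at 0.22 and Tiparp at 0.26, and clock genes from Per3 at -0.09 and Csnk1e at -0.05 to Arntl at 0.23 and Rorb at 0.24. Cell-cycle Mcm2 and Mcm3 were at -0.54 and -0.43, with Cdc7 at 0.30 and E2f1 at 0.32, and p53 targets ranged from Pmaip1 at -0.45 to Sesn2 at 0.26, with Ddit4 at -0.16 and Polk at 0.19.

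Ribosomal protein genes had 32 of 43 members higher in sign (camera adjusted p = 0.335), with Rps27 at 0.61, Rpl41 at 0.20, Rps6 at -0.54 and Rpl37 at -0.22. Their estimated correlation was 0.40, and the list was called in 2 of 19 alternatives (lowest camera adjusted p = 0.000143). Proteasome genes ranged from Psmb9 at -0.35 and Psmc1 at -0.12 to Psmb4 at 0.16 and Psmb2 at 0.29, and splicing factors from Snrpa1 at -0.23 and Srsf10 at -0.24 to Srsf5 at 0.18 and Hnrnpdl at 0.17. The splicing factor list was called in 1 of 19 alternatives (lowest camera adjusted p = 0.0484). Of 23 genes linked to synuclein and Parkinson's disease, 19 were higher in sign (camera adjusted p = 0.562), led by Uchl1 at 0.20 and Hspa8 at 0.13, with Siah1a at -0.23 and Vps35 at -0.08. Cornified envelope genes, partners of periplakin, had Krt1 at -0.35, Tgm2 at -0.30, Evpl at 0.34 and Plec at 0.13.

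Lists of tissues that a dissection can include did not pass. The pituitary and pineal list had a median of -0.67 over 8 genes (camera adjusted p = 0.335), with Pomc at -2.09 (SE 1.03), Prl at -2.16 (SE 1.44), Chga at 0.03 and Chgb at 0.02. That median was -0.19 without the dim filter, -1.81 with the filter at the 60th percentile, -0.41 with a pseudocount of 1 and 0.01 without wild type 1. The list passed without heterozygous 3 (camera adjusted p = 0.0484) and without wild type 2 (camera adjusted p = 0.0251), both at the preset correlation. Over all 6 arrays its estimated correlation was 0.37. Camera with that correlation gave an adjusted p of 0.844, and fry gave 0.947. Choroid plexus and ependymal genes ranged from Tmem212 at -0.34 and Ace at -0.30 to Mlf1 at 0.24 and Kcnj13 at 0.26. Meningeal genes ranged from Mgp at -0.20 and Ogn at -0.22 to Col3a1 at 0.26 and Foxc1 at 0.32, and blood genes from Hbb-b2 at -0.19 and Alas2 at -0.09 to Bpgm at 0.07 and Ngp at 0.14.

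Xist, the RNA that coats the inactive X chromosome in females, was bright on all 6 arrays, although the labels call the mice male. Its brightest probe set measured 1793 to 2606. The 13 probe sets of 6 Y-linked genes, among them Kdm5d, Eif2s3y and Uty, lay between 0.189 and 18.9, near or below the limit for dim probe sets of 18.4. Xist was the single measured gene of the sex-linked list, and its log2 difference was 0.27 (SE 0.11).

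**Figure D3:**
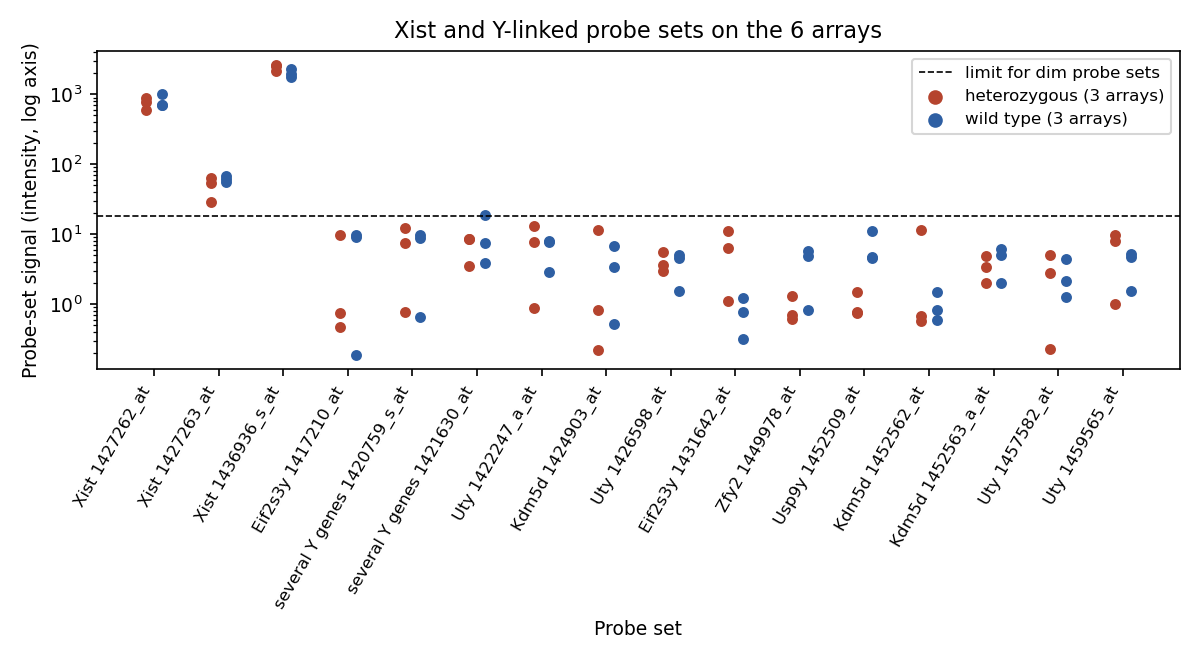
Signal (intensity, log axis) of the Xist and Y-linked probe sets, with 1 point per array for 3 heterozygous and 3 wild-type arrays and a dashed line at the limit for dim probe sets (18.4). The brightest Xist probe set sits between 1793 and 2606 on all arrays, and the Y-linked points reach at most 18.9.

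Array quality was similar between genotypes in most measures. The 3' over 5' ratio of the beta-actin control probe sets was 1.65 ± 0.0642 in heterozygous and 1.67 ± 0.0297 in wild-type brains (n = 3 each, exact permutation p = 0.6). For Gapdh it was 0.750 ± 0.00446 against 0.724 ± 0.00986 (n = 3 each), with no overlap and the smallest exact permutation p the design allows, 0.1. The 18S ribosomal RNA control signal was 80.3, 114.8 and 114.3 on the heterozygous arrays and 94.4, 178.9 and 100.4 on the wild-type arrays (exact permutation p = 0.7).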

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

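The 18S covariate was chosen after the data had been seen, and all other alternatives were planned. No called result reversed. Lists without a call turned direction in part, most of all synaptic vesicle genes, which kept it in 7 of 19 alternatives. The 3 higher and 1 lower probe sets became 1 and 0 without the dim filter, where more probe sets were tested, 1 and 0 by eBayes without trend, 0 and 0 without moderation of the t statistic (1369 at an unadjusted p below 0.05), 3 and 2 with quantile normalization, and 7 and 4 with the 18S signal as covariate. Leaving out single arrays gave 1 to 6 higher and 0 to 8 lower. Mtmr7 was called in 17 of 18 alternatives, 1439170_at in 11, and Prune2 and Yaf2 in 10 each. Their directions held in all 18, but most alternatives could not change them, since the genotypes did not overlap at these probe sets. Where tested, both Pphln1 probe sets stayed on the same side of the threshold, from 0.01 to 0.19 for 1434822_at and from -0.48 to -0.20 for 1435766_at, which the dim filter at the 60th percentile removed. The 1306 probe sets at an unadjusted p below 0.05 became 2250 without the dim filter. The 31 with a log2 difference of 1 or more became 174 with a pseudocount of 1, 14 with 64, 55 with the 18S covariate, and 36 to 64 with single arrays left out.

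The share of genes near Pphln1 at p below 0.05 was no longer above other genes by Fisher's exact test without the dim filter (7.22%), without moderation (7.65%), with the 18S covariate (8.74%), in the 20 Mb window (5.60%) and with the replicate block (9.84%); with single arrays left out it ran from 6.01% to 11.5%. The count of lists past the threshold, 1, became 0 with an estimated correlation and 0 to 5 with single arrays left out. The cause of these shifts was not tested. Replicate numbers were not taken to pair the arrays, since the deviations of same-numbered arrays correlated at 0.08, 0.20 and -0.02, and 1 of the 3 heterozygous arrays correlated best with its own number. With the replicate block, 3 probe sets were higher and 2 lower, the second being H1f2.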

Other observations

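The test on array scaling and the split tests for gene lists and for genes near Pphln1 were set before their results were seen. The split tests for probe-set counts and all other tests here were chosen after the patterns had been noticed.

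Hormone genes of the pituitary varied between single brains far more than between genotypes. Growth hormone (Gh) measured 46.7, 43.5 and 2696 in the heterozygous brains and 7567, 310.9 and 158.3 in the wild-type brains. Prolactin (Prl) followed with 76.7, 38.8 and 3729.5 against 8306, 415.4 and 456.1. Cga, the common subunit of the glycoprotein hormones, reached 99.0 in heterozygous 3 and 889.5 in wild type 1 and stayed at or below 4.99 elsewhere, and Pomc reached 4380.1 in wild type 1. The secretory granule genes Chga and Chgb, which neurons also express, lay at 0.03 and 0.02 on the log2 scale between genotypes.

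Yaf2, Zcrb1 and Gxylt1 were lower in heterozygous brains beside a Pphln1 signal that passed no test. Array scaling is argued against by the log2 array medians, which averaged 5.61 in heterozygous and 5.58 in wild-type brains. Median centring could therefore move the differences only slightly. The median of the 3 genes lay at -0.54 or below under quantile normalization and median centring. A longer segment of DNA from another strain, carried along with the targeted allele, could alter neighbours on a wider scale, but 5 of 61 other genes within 5 Mb (8.20%) had a p below 0.05, which did not differ from other genes by Fisher's exact test (p = 0.192) and leaves it open. A sequence difference under the probes also stays open: the second Yaf2 probe set lay at -7.03 in units of its SE, but probe sequences were not used here, and the probe sets could share probes. An effect of the disrupted allele on its neighbours is the biological explanation the design offers, and it was not tested.

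Xist was bright and Y-linked genes were near background on all 6 arrays labelled male. Female brains are a candidate explanation: the highest mean of a Y-linked probe set was 8.48, under the dim limit of 18.4, and Xist lay at least 97.5 times above that limit. A first criterion, that every Y-linked value lie under the limit, was missed by 1 of 78 values (18.9) and was replaced by means and by the share above the limit, 1.28% against 10.1% for all dim probe sets. By that first criterion female brains would not have fitted and a mixture with male RNA would have, because of that 1 value. The criterion in use was chosen after seeing the data. On the array with that value, wild type 2, the Eif2s3y, Kdm5d and Uty probe sets measured 0.189 to 8.04. Those values argue against more than a small share of male RNA there. Y-linked probe sets that fail to hybridise would leave Xist near background in males, which its lowest value of 1793 argues against, and a small share of male RNA cannot be told apart from none, because signals up to 18.9 lie in the noise.

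Of the 10 ways to split the 6 arrays 3 against 3, setting heterozygous 1, wild type 1 and wild type 3 against the rest called 67 probe sets, against 4 for genotype; Scn2b at 1430648_at, for example, measured 935.4, 915.8 and 829.9 on those arrays and 35.4 to 51.1 on the others. A batch of RNA or labelling marked by the low 18S signal of the same 3 arrays is a candidate cause that stays open. The called genes were over-represented on chromosomes 9, 11 and 13, with 10 on chromosome 13 (Fisher's exact adjusted p = 0.000486). That held with genes in the same 1 Mb counted once (Fisher's exact adjusted p = 0.0154, 0.000124 and 0.00379), which a batch alone would not predict. Among genes at p below 0.01, however, chromosomes 17, 9 and 14 were over-represented in other splits (Fisher's exact adjusted p = 0.000922, 0.00734 and 0.0332). Over-representation was thus not particular to this split, which was picked as the largest of the 10, and cannot decide about a batch. A criterion that ruled out such enrichment in other splits, set and dropped after the data were seen, had also left the batch open. Segments of 2 strains that differ between the animals are another candidate, a hypothesis found and tested on the same data, and it stays open too. All 3 chromosomes followed the same split, although separate chromosomes are inherited independently in littermates, as the mice are described. The 10 genes on chromosome 13 spanned 64.8 Mb, with at most 4 within 10 Mb. Around Mtmr7 on chromosome 8, 3 of 22 genes within 5 Mb (Lonrf1, Frg1 and Dlc1) had a p below 0.05 between genotypes (Fisher's exact p = 0.0693), which leaves a segment there open. Unc13a and Rab3a also lie on chromosome 8, and whether they share a segment with Mtmr7 was not tested. Among genes at p below 0.01 between genotypes, no chromosome was over-represented (lowest Fisher's exact adjusted p = 0.444, for chromosome 15).

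With 10 splits a share under 0.05 cannot be reached. For probe sets past the adjusted threshold, 2 of the 10 splits reached the 4 of the genotypes, and the highest other was 67. For probe sets at an unadjusted p below 0.05, 5 splits reached 1306, and the highest other was 2123. For gene lists, all 10 splits reached the 1 list called between genotypes, and the highest other was 7. For genes within 10 Mb of Pphln1, 1 split, the real one with 15, was highest, and the highest other was 14.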
